A study of Mus musculus with 16 samples.

How the data were processed

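The values are the deposited tables of normalized expression, which per the file headers hold RPKM (reads scaled to gene length and to the mapped reads of the library) for each gene and library, with reads mapped to the mouse genome build mm10 by TopHat and RPKM calculated in Partek. The submitters' notes give TopHat2 2.1.1, bcl2fastq 2.20.0.422 and Partek, but the sources used here name neither the gene annotation nor the rule for reads that map to several places. Each table lists 24981 genes, of which 23236 are above 0 in at least 1 Fvb/N library and 20838 in at least 1 library of the Dlx3 table. The Fvb/N and Dlx3 tables were normalized apart, so levels are compared within a table only.

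The authors' deposited comparison tables give, per the file headers, group means as log2 of RPKM plus 0.1, a linear ratio of the group means, a p-value from an analysis of variance in Partek, and a q-value whose method is not named in the sources used here. Those values are quoted only where the authors' deposited table is named.

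For the fits, RPKM plus 1 was taken to log2, so the fold changes understate the change of genes with low values. A gene was tested where RPKM reached 1 in at least 4 libraries (Fvb/N table, 11608 genes) or at least 2 libraries (Dlx3 table, 12146 genes). Groups were compared in limma 3.58.1 (R 4.3.3) with an intensity trend, with 6 residual and 3.2 prior degrees of freedom in the Fvb/N fit and 4 and 4.8 in the Dlx3 fit. Adjusted p is the Benjamini-Hochberg value over all genes tested, and a gene is called at an adjusted p under 0.05. Rose and fell are used of called genes only. The median change of all genes is given once for each comparison, since RPKM are relative values. Every direction was also taken after rescaling the libraries by the median ratio and after quantile normalization. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

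The comparisons, the model, the gene lists and the alternative settings planned were fixed before the data were examined. The lists come from textbook knowledge of the epidermis, its other cell types, chromatin complexes and general processes. Lists with at least 3 measured members were tested with limma's camera with a preset correlation of 0.01 between genes, and adjusted over the lists tested in the comparison. Camera asks whether a list moved relative to the other genes. With the correlation estimated from the libraries, 0 of the 25 list calls in Fvb/N hold (3 lists at an unadjusted p under 0.05), 1 of 26 in the Dlx3 wild-type (WT) fractions, 9 of 27 in the Dlx3 knockout (KO) fractions, 7 of 26 for KO against WT in basal cells, 0 of 24 in suprabasal cells (13 at an unadjusted p under 0.05), 6 of 25 averaged over both fractions and 0 of 23 in the interaction (9 at an unadjusted p under 0.05).

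Genes are named by a rule fixed in advance. Dlx3 is given in every library. Krt5, Krt14, Itga6, Trp63, Krt1, Krt10, Lor, Flg, Ivl and Mki67 are taken in every comparison; Flg is not analysed here. From each comparison come up to 6 called genes with the largest rise and up to 6 with the largest fall, among those with a mean of at least 5 RPKM in the higher group and no overlap between the groups' libraries. From each list that passed, and from the epidermal, regulator and chromatin lists in any case, come up to 4 members with the smallest p. Predicted genes and olfactory receptors were passed over, and a few genes that the rule takes are not reported here. Values of near-identical genes (the Lce1, Sprr, globin, Stfa2, Serpinb3a, Krt6b and Dsg1a families) are uncertain, because reads can map to several of them.

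Errors are the standard errors of limma's log2 fold change, and ± is the standard deviation (SD) between libraries of a group. These p-values measure only the spread between the libraries of a group, which may be technical. Same-numbered libraries of the Dlx3 table's groups deviate from their group means with correlations across genes of 0.02, 0.02, 0.06 and −0.02. These values show no pairing by replicate number. They cannot exclude it, since the libraries of a Dlx3 group differ by little more than counting noise. In the Fvb/N table the correlations of same-numbered basal and suprabasal libraries are 0.51, 0.57, 0.56 and 0.12. Differently numbered basal and suprabasal libraries within replicates 1 and 2 are at 0.36 and 0.59, and within replicates 3 and 4 at 0.01 and 0.47. Whether the numbers pair the Fvb/N libraries therefore stays open, and a fit with the replicate number as a block was also made there. In a check with changes planted in simulated values that have the real means and spreads, the Fvb/N fit recovered 74% of 2-fold and 98% of 4-fold changes, and 11 of 162 calls were unchanged genes. The corresponding check of KO against WT in basal cells recovered 72% of 1.2-fold and 94% of 1.5-fold changes, with 3 unchanged genes among 139 calls. For suprabasal cells it recovered 70% and 92%, with 8 unchanged genes among 145 calls. In the same check camera called the list shifted by 1.5-fold and 0 of 40 unchanged lists. The simulated genes vary independently, so the check does not show how camera behaves with the correlation between real genes. The check also changed fewer genes than the corresponding real fits call, which makes its adjusted p stricter. Its recovery rates therefore need not hold for the real fits.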

Results

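Newborn mouse epidermis (days p0 to p2) was separated on Percoll into basal and suprabasal keratinocytes, and total RNA was sequenced from 16 libraries in 6 groups. Fvb/N mice gave 4 basal and 4 suprabasal libraries. Dlx3 WT and KO mice, of mixed CD-1 and C57BL/6 background, gave 2 libraries per genotype and fraction. Basal cells attach to the basement membrane and divide, and suprabasal cells stop dividing and build the cornified barrier. The estimated depth is 54.3, 54.3, 52.9 and 45.7 M reads for Fvb/N basal libraries 1 to 4 and 46.1, 54.9, 54.6 and 61.8 M for suprabasal libraries 1 to 4. It is 42.1 and 42.2 M for WT basal, 36.7 and 37.7 M for KO basal, 39.1 and 34.6 M for WT suprabasal, and 40.8 and 33.8 M for KO suprabasal. M stands for mega, and these depths were estimated from the smallest steps between length-adjusted RPKM of genes with a single transcript.

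The replicates differ in kind between the tables. The paired libraries of a Dlx3 group differ by a median of 2.2% to 2.5% per gene, and the Fvb/N libraries of a group by 5.6% to 38.4%. Both sexes' genes are present in all Dlx3 libraries: Xist, the RNA of the inactive X chromosome, lies between 37.6 and 57.0 RPKM and the Y-linked Ddx3y between 5.45 and 11.6 RPKM. For Fvb/N, the sample labels give run code 180629 to replicates 1 and 2 and a later run code to replicates 3 and 4 of both fractions. The header of the RPKM table gives the first code to all basal and the other to all suprabasal libraries, in which case run and fraction cannot be told apart. All Dlx3 libraries carry run code 190124.

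Dlx3, a homeobox transcription factor of the upper epidermis, was lower in KO than in WT in both fractions but not absent. In basal cells its RPKM was 11.16 and 11.01 in WT and 2.35 and 2.16 in KO, a log2 fold change of −1.89 (SE 0.07, adjusted p = 3.97e-07). In suprabasal cells Dlx3 was at 7.87 and 6.92 RPKM in WT and 2.64 and 2.24 in KO, a log2 fold change of −1.29 (adjusted p = 6.01e-06). In the authors' deposited table the KO to WT ratio of Dlx3 is 0.21 (q = 0.00547) in basal and 0.338 (q = 0.00488) in suprabasal cells. In Fvb/N, Dlx3 was at 10.51, 8.17, 11.35 and 9.53 RPKM in basal libraries 1 to 4 and 11.05, 9.95, 7.04 and 14.98 RPKM in suprabasal libraries 1 to 4. Its suprabasal to basal log2 fold change in Fvb/N is 0.08 (adjusted p = 0.746), or 0.70 (adjusted p = 0.033) after rescaling. In WT it fell by 0.53 (adjusted p = 6.17e-05), and the fall of Dlx3 is not called after rescaling (−0.09, adjusted p = 0.27). In KO the fraction change of Dlx3 is 0.08 (adjusted p = 0.315), or 0.41 (adjusted p = 0.000628) after rescaling.

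**Figure D1:**
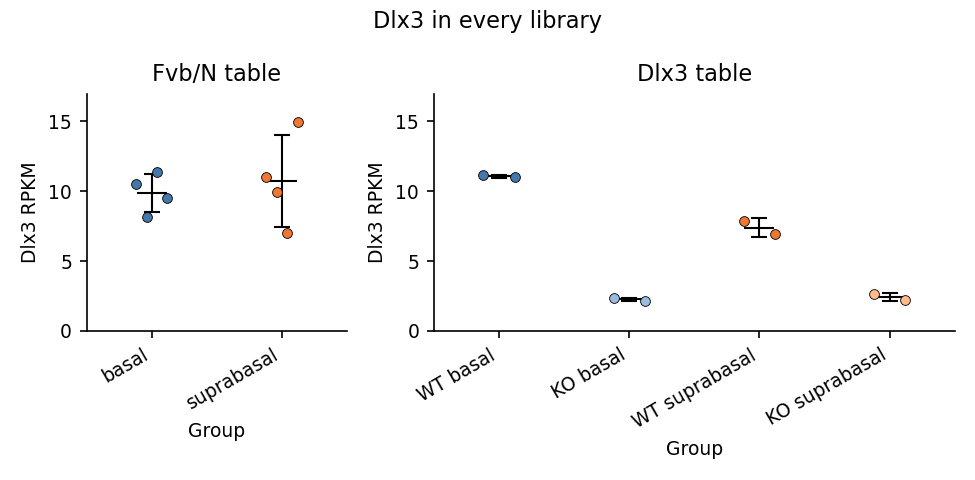
RPKM of Dlx3 (linear axis) in the Fvb/N table (left) and the Dlx3 table (right), by fraction and genotype; points are libraries and bars the mean ± SD. Dlx3 averages 11.1 RPKM in WT basal and 2.26 RPKM in KO basal libraries.

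Fvb/N suprabasal cells had much less RNA of the genes that attach basal cells to the basement membrane, and more of the genes of the cornified barrier. Col17a1, a hemidesmosome collagen, fell by 4.75 log2 units (SE 0.634, n = 4 per fraction, limma adjusted p = 0.000192; 447 ± 23.6 to 26.3 ± 33.7 RPKM). The basal keratins Krt5 and Krt14 fell by 4.28 and 3.08, and Trp63, the regulator of epidermal stem cells, fell by 2.42. Mki67, a marker of dividing cells, fell by 3.65 (SE 0.419; 43.3 ± 4.73 to 3.31 ± 3.44 RPKM). Lor, the main protein of the cornified envelope, rose 29.2-fold (log2 4.87, SE 0.904, adjusted p = 0.00108; 177 ± 165 to 3641 ± 1930 RPKM).

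All 29 measured genes of the basal keratinocyte list fell (also 29 adjusted over the list alone), with a median log2 fold change of −3.47. The laminin chain Lamb3 (−4.40), the integrin Itgb4 (−4.30), the laminin receptor Bcam (−4.20) and Itga6 (−4.05; 99.1 ± 21.8 to 8.60 ± 11.6 RPKM) are among them. In suprabasal library 3 Col17a1 is at 76.6 RPKM, against 6.62 to 14.5 in the other suprabasal libraries. Camera gives the basal list an adjusted p of 0.00019 (adjusted p = 0.64 with an estimated correlation). Agrn, a basement membrane proteoglycan, fell by 4.29. Division genes fell as a group: 44 of 45 genes of the G2 and M phases and 47 of 49 of the S phase (44 and 47 adjusted over the list alone), among them Cdc25b (−2.79), a phosphatase that starts mitosis, and Cdc45 (−2.27), part of the replication helicase. Their camera adjusted p-values are 7.3e-08 and 1.1e-07 (adjusted p = 0.64 with an estimated correlation for both).

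In the granular and cornified list 30 of 31 genes rose and 1 fell (the same counts adjusted over the list alone), with a median of 3.10 and a camera adjusted p of 4.3e-22 (adjusted p = 0.519 with an estimated correlation). Examples are Cnfn (24.8-fold), a cornified envelope protein, Flg2 (10.7-fold), a filaggrin relative, and Ivl (15.5-fold, adjusted p = 0.00102), an envelope precursor. Of 22 genes of the spinous layer 21 rose (21 adjusted over the list alone), with a median of 1.79 and a camera adjusted p of 3.2e-14 (adjusted p = 0.545 with an estimated correlation). The spinous keratins Krt1 and Krt10 rose 4.72-fold (SE 0.814, adjusted p = 0.0315) and 4.96-fold (SE 0.856, adjusted p = 0.0339), from uneven basal levels of 9157 ± 7800 and 11190 ± 9490 RPKM. Both keratins together take 10.7%, 11.8%, 1.7% and 1.8% of the RPKM sum in basal libraries 1 to 4, and 23.2%, 22.5%, 15.4% and 20.7% in suprabasal libraries 1 to 4. The call on Krt10 is lost with the replicate number as a block (adjusted p = 0.0566, and 0.0479 for Krt1). Both keratins lose the call without a filter, under quantile normalization, without suprabasal libraries 3 and 4, and when any of basal 3 or 4 or suprabasal 1, 2 or 4 is left out, where the adjusted p of Krt1 is 0.127, 0.102, 0.0672, 0.0587 or 0.0693 and that of Krt10 0.14, 0.11, 0.0718, 0.0643 or 0.0727. The 8 measured Sprr genes, small envelope proteins whose reads may be shared, all rose (8 adjusted over the list alone, Sprr1a 10.4-fold, Sprr4 5.23-fold; camera adjusted p = 1.3e-08, and adjusted p = 0.519 with an estimated correlation). Of 4 Lce genes, late envelope proteins, 0 passed the limma test, also adjusted over the list alone (1 at an unadjusted p under 0.05), and Lce1m is at 2.02 (adjusted p = 0.073). With the replicate block Lce1m is called (adjusted p = 0.000738), as it is with the run code as a term, within each run code, without suprabasal library 1 (adjusted p = 0.0274) or 2 (adjusted p = 0.0329), and after rescaling or quantile normalization, where 2 and 4 of the Lce genes are higher. Camera gives the list an adjusted p of 0.014 (adjusted p = 0.592 with an estimated correlation).

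Barrier lipid genes rose in 29 and fell in 2 of 34 cases (30 and 2 adjusted over the list alone), with a median of 1.66 and a camera adjusted p of 8e-18 (adjusted p = 0.545 with an estimated correlation). Aloxe3, a lipoxygenase of the barrier, rose 9.16-fold and Ugcg, which makes glucosylceramide, 2.78-fold. The cholesterol synthesis list rose in 16 and fell in 1 of 23 genes (16 and 1 adjusted over the list alone, Pmvk 3.34-fold), with a camera adjusted p of 3.9e-09 (adjusted p = 0.546 with an estimated correlation). Alarmin and stress genes rose in 21 and fell in 3 of 26 (21 and 3 adjusted over the list alone), with Stfa2, a cysteine protease inhibitor, at 19.4-fold, Fabp5, a fatty acid binding protein, at 6.67-fold and Il1f9, a cytokine, at 3.72-fold. Their camera adjusted p is 1.5e-13 (adjusted p = 0.519 with an estimated correlation). Desmosome genes rose in 5 and fell in 3 of 12 (5 and 3 adjusted over the list alone): Dsc1, the upper-layer desmocollin, rose 6.31-fold and Dsg2, the basal desmoglein, fell by 3.24. Their camera adjusted p is 0.0067 (adjusted p = 0.552 with an estimated correlation).

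Hair follicle genes rose in 19 and fell in 12 of 34 (19 and 12 adjusted over the list alone), with a camera adjusted p of 7.3e-08 (adjusted p = 0.546 with an estimated correlation). Krt71, a keratin of the inner root sheath, rose most of all named genes, 38.5-fold (log2 5.27, SE 0.171, adjusted p = 1.67e-06; 0.405 ± 0.102 to 54.1 ± 12.9 RPKM), and its neighbours in that sheath, Krt27 and Krt25, rose 27.4-fold and 22.9-fold. In the authors' deposited table the ratio of Krt71 is 107, and that of Lor 29.6. The melanocyte list fell in 12 of 13 genes (12 adjusted over the list alone, Pmel −3.06), with a camera adjusted p of 0.028 (adjusted p = 0.64 with an estimated correlation). Of 18 Langerhans and myeloid genes 13 fell (13 adjusted over the list alone), with a camera adjusted p of 0.27, or 0.015 with the replicate block. The fibroblast list rose in 2 and fell in 7 of 14 (2 and 7 adjusted over the list alone), with a median of −1.46, a mean of −0.90 and a camera test that points up (adjusted p = 0.48). Suprabasal libraries 3 and 4 have 21583 and 21766 genes above 0, against 18816 to 19194 in the other Fvb/N libraries, and their median fibroblast gene is at least 3.78 times as high as in suprabasal libraries 1 and 2. Without both of them 8942 genes are called between the fractions.

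**Figure D2:**
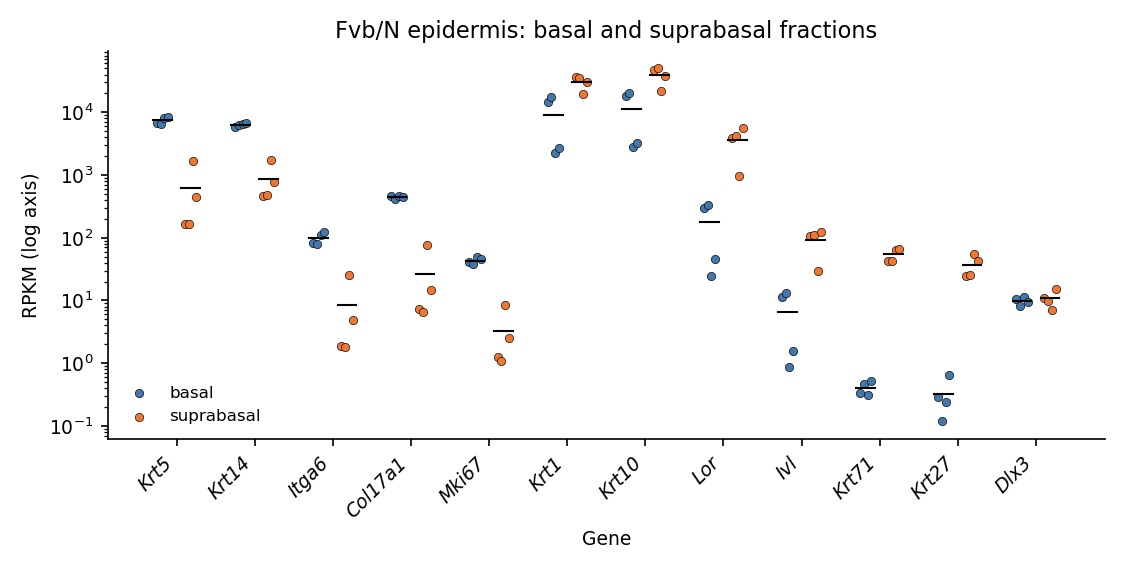
RPKM (log axis) of marker genes in Fvb/N basal (blue) and suprabasal (orange) libraries; points are libraries and black lines means. Krt5 falls from 7441 to 620.0 RPKM and Krt71 rises from 0.405 to 54.1 RPKM between fractions.

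Chromatin genes fell with most other genes of the Fvb/N suprabasal fraction. Uhrf1, a partner of the maintenance DNA methyltransferase, fell by 3.49 (44.8 ± 4.81 to 3.60 ± 2.8 RPKM), Dnmt1, that methyltransferase, by 1.38, and Dnmt3a by 2.18. In the DNA methylation list 14 of 16 genes fell (14 adjusted over the list alone), in the SWI/SNF remodeller list 24 of 26 (24), in the KMT2 list 18 of 21 with 1 higher (18 and 1), and in the Polycomb list 27 of 34 with 2 higher (27 and 2), the counts in parentheses adjusted over the list alone. Phc2, a Polycomb subunit, fell by 1.82, Actl6a, a SWI/SNF subunit, by 1.53, and the methyltransferase Suv39h1 by 2.28. The camera adjusted p-values are 0.048, 0.0019, 0.028 and 0.031 (adjusted p = 0.64 with an estimated correlation for each of the 4 lists). After rescaling 10 genes of the DNA methylation list are lower and 1 higher, 18 and 2 of SWI/SNF, 13 and 2 of KMT2, and 18 and 7 of Polycomb, with 9 and 1, 18 and 2, 13 and 1, and 16 and 7 after quantile normalization. Regulators of the epidermis split: 11 of 43 rose and 21 fell (11 and 21 adjusted over the list alone). Rora (2.43-fold), a nuclear receptor, was higher and Lef1 (−3.08), a Wnt effector, and Grhl2 (−2.14) were lower. The regulator list's median is −0.47 and its mean −0.28, camera points up (adjusted p = 0.034, and adjusted p = 0.546 with an estimated correlation), and the median is 0.08 after rescaling, with 19 higher and 11 lower, or 19 and 17 after quantile normalization. Of the other Dlx genes, Dlx5 rose 3.94-fold and Dlx4 fell by 1.103.

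In all, 8584 of 11608 genes were called in Fvb/N, 1554 higher and 7030 lower in suprabasal cells, with a median log2 fold change of −0.55 over all genes. After rescaling it is 3846 higher and 3946 lower, so the share of calls that are higher moves from 18.1% to 49.4%. With the labels' run code as a term 9074 genes are called, and within the earlier and the later run code 9686 and 6573. With the replicate block 8827 are called, and the glycolysis and sebaceous lists, at camera adjusted p-values of 0.048 and 0.033 (adjusted p = 0.546 with an estimated correlation for both), are at 0.071 and 0.069. Both tests point up, where the medians are −0.02 and 0.05, the means −0.22 and −0.13, and the medians after rescaling 0.66 and 0.55. Ribosomal protein genes, of which 0 of 78 were called by limma (also 0 adjusted over the list alone, and 2 at an unadjusted p under 0.05), have a median of 0.22 with a camera adjusted p of 1e-09 (adjusted p = 0.64 with an estimated correlation), and 63 are higher after rescaling but 4 higher and 1 lower after quantile normalization.

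The Dlx3 table repeats the comparison in WT and KO mice, with 2 libraries per group. In WT suprabasal cells Spink5, a protease inhibitor of the granular layer, was 70.2-fold higher (0.922 to 134 RPKM), followed by Lypd5 (58.1-fold), Hal (55.1-fold), the enzyme that makes urocanic acid, Cyp2b19 (54.0-fold), Susd2 (51.1-fold) and Krt78 (49.6-fold). Krt1 rose 11.9-fold (limma adjusted p = 2.14e-13, n = 2 per fraction; 1583 ± 5.3 to 18830 ± 46.7 RPKM), Krt10 12.6-fold, Lor 21.3-fold and Ivl 20.7-fold. Krt5 fell by 1.13 (8491 ± 168 to 3889 ± 37.3 RPKM), Krt14 by 0.95, Itga6 by 0.96, and Trp63 and Mki67 by 1.07 each. Hbb-b1, a globin of red cells, fell by 4.88 (30.7 to 0.0773 RPKM) and the other globins Hba-a1 and Hba-a2 by 4.03 and 3.91. In WT all 5 erythroid genes fell (5 adjusted over the list alone, camera adjusted p = 0.037, and adjusted p = 0.192 with an estimated correlation).

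Of the WT lists, granular and cornified genes rose in 30 and fell in 1 of 31 (the same adjusted over the list alone, camera adjusted p = 1.5e-27, and adjusted p = 0.0511 with an estimated correlation). Spinous genes rose in 19 and fell in 2 of 21 (the same adjusted over the list alone, adjusted p = 1.1e-18, and adjusted p = 0.0576 with an estimated correlation). Barrier lipid genes rose in 33 and fell in 2 of 35 (the same adjusted over the list alone, adjusted p = 2.4e-26, and adjusted p = 0.0202 with an estimated correlation), with Dgat2, a triglyceride synthase, at 25.0-fold and Acer1, a ceramidase, at 16.9-fold. Desmosome genes rose in 10 and fell in 2 of 12 (the same adjusted over the list alone, Dsc1 29.4-fold; adjusted p = 1.3e-07, and adjusted p = 0.071 with an estimated correlation). Basal keratinocyte genes fell in 26 and rose in 2 of 29 (the same adjusted over the list alone, median −0.91; adjusted p = 0.00079, and adjusted p = 0.071 with an estimated correlation). All 45 genes of the G2 and M phases fell (45 adjusted over the list alone, Cdc20 −1.43; adjusted p = 2.2e-07, and adjusted p = 0.071 with an estimated correlation). Of 49 S phase genes 48 fell and 1 rose (the same adjusted over the list alone, Pcna −1.25; adjusted p = 5.8e-06, and adjusted p = 0.0578 with an estimated correlation).

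Ribosomal protein genes fell in all 78 cases in WT (78 adjusted over the list alone, Rps23 −0.92; camera adjusted p = 4.6e-09, and adjusted p = 0.375 with an estimated correlation). SWI/SNF genes fell in all 26 cases (26 adjusted over the list alone, Smarce1 −1.03; adjusted p = 0.0021, and adjusted p = 0.071 with an estimated correlation), but in 16 with 4 higher after rescaling. Of single regulators in WT, Grhl1, a grainyhead factor, rose 5.63-fold, and Lef1 (−1.65), Tfap2b (−1.42), the Polycomb methyltransferase Ezh2 (−1.25), Bmi1 (−1.17) and Uhrf1 (−1.17) fell. Lce genes rose in 6 and fell in 0 of 15 (4 and 0 adjusted over the list alone, Lce1c 1.42-fold; camera adjusted p = 0.0014, and adjusted p = 0.146 with an estimated correlation), but in 13 with 0 lower after rescaling and in 12 with 1 lower after quantile normalization. In WT 10881 of 12146 genes were called, 2336 higher and 8545 lower, with an all-gene median of −0.40. After rescaling the WT counts are 4895 higher and 4765 lower, and at a change of at least 2-fold 664 higher and 849 lower become 1082 and 68.

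In KO mice Spink5 (54.2-fold), Hal (40.6-fold), Lypd5 (39.8-fold) and Serpina12 (30.5-fold) were among the genes that rose most in suprabasal cells. Krt1 rose 9.02-fold, Krt10 9.81-fold, Ivl 19.6-fold and Lor 9.98-fold (240 ± 1.05 to 2408 ± 90 RPKM), while Krt5 fell by 1.33, Krt14 by 1.05, Itga6 by 1.07, Trp63 by 1.27 and Mki67 by 1.11. Granular and cornified genes rose in 29 and fell in 1 of 31, spinous genes rose in 19 of 21 with 0 lower, and barrier lipid genes rose in 33 and fell in 1 of 35, with the same counts adjusted over the list alone. Their camera adjusted p-values are 7.8e-26, 4.9e-19 and 3.8e-27 (adjusted p = 0.0467, 0.0467 and 0.0187 with an estimated correlation). Cholesterol synthesis genes rose in 19 and fell in 3 of 23 (the same adjusted over the list alone, Sqle log2 1.99; adjusted p = 2.9e-12, and adjusted p = 0.0467 with an estimated correlation). Basal keratinocyte genes fell in 27 of 29 (27 adjusted over the list alone, adjusted p = 0.00015, and adjusted p = 0.0468 with an estimated correlation). In KO 0 of 15 Lce genes rose and 10 fell (the same adjusted over the list alone, median −0.36; Lce1h −0.86), but the list's median turns to 0.09 after rescaling and camera gives an adjusted p of 0.82.

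Marker RNA of cells other than keratinocytes also differed between the KO fractions. Langerhans and myeloid genes rose in 19 of 22 (18 adjusted over the list alone), with C1qa, a complement gene of macrophages, at 1.95-fold and a camera adjusted p of 7.5e-10 (adjusted p = 0.0467 with an estimated correlation). In WT that list rose in 2 and fell in 11 of 22 (1 and 8 adjusted over the list alone, camera adjusted p = 0.26), while after rescaling 15 are higher and 0 lower. In KO fibroblast genes rose in 8 and fell in 7 of 15 (the same adjusted over the list alone): Col3a1, a dermal collagen, rose 8.72-fold (0.729 to 14.1 RPKM) and Dcn, decorin, fell by 1.84 (115 to 31.4 RPKM). After rescaling 12 of these fibroblast genes are higher and 3 lower. The fibroblast list's camera adjusted p is 0.0071 (adjusted p = 0.119 with an estimated correlation). In KO 10883 genes were called, 2416 higher and 8467 lower, with an all-gene median of −0.39, against 4832 and 4700 after rescaling.

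Fvb/N and WT calls overlap. Of 11447 genes tested in both, 7544 were called the same way: 1224 higher (286.2 expected by chance) and 6320 lower (4944.6 expected), and 345 were called in opposite directions (630.0 without Fvb/N suprabasal library 3, 222 without suprabasal library 2). Krt1, Krt10, Lor and Ivl are higher, and Krt5, Krt14, Itga6, Trp63 and Mki67 lower, in the suprabasal fraction of both. Across genes, which are not independent replicates, the log2 fold changes have a Spearman rho of 0.71 and a Pearson r of 0.78. After rescaling 5731 genes are called the same way, 2840 higher and 2891 lower, with 789 opposite. Each was compared with its own table's basal cells, and the size of the Krt5 fall (4.28 in Fvb/N, 1.13 in WT) is set beside the other without a test.

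The basal fraction of KO mice had more RNA of cornified envelope genes than that of WT mice. Lor was 3.87-fold higher (log2 1.95, limma adjusted p = 3.33e-08, n = 2 per genotype; 61.5 ± 4.21 to 240 ± 1.05 RPKM) and Crct1, a gene beside the Lce cluster, 3.89-fold (6.67 ± 0.474 to 28.8 ± 0.563 RPKM). Lce1m rose 3.96-fold (SE 0.057; 14.03 to 58.5 RPKM) and Lce1b 3.83-fold. The spinous keratins Krt1 and Krt10 rose by 0.55 and 0.56 in log2, while Krt5 (log2 −0.00, adjusted p = 0.978), Itga6 (−0.01, adjusted p = 0.883), Trp63 (0.02, adjusted p = 0.738) and Mki67 (−0.02, adjusted p = 0.785) were not called. Ivl rose 1.73-fold. Krt14 is at log2 0.11 (adjusted p = 0.0231), a call lost in the fit of basal libraries alone, without a filter, without the intensity trend, under quantile normalization and with any 1 of the 8 libraries left out (adjusted p from 0.0504 to 0.118). In the authors' deposited table the basal KO to WT ratio is 3.91 for Lor and 4.28 for Crct1. In KO basal libraries Lor and Krt1 (2322 RPKM) stay far below their WT suprabasal means of 1330 and 18830 RPKM, while Crct1 lies above its own (15.2 RPKM). A higher share of suprabasal cells in the KO basal fraction could give rises like those of Lor and Krt1, which was not tested outside the Lce genes.

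All 15 measured Lce genes rose in KO basal cells (15 adjusted over the list alone), with a median of 1.79 and a camera adjusted p of 4.5e-37 (adjusted p = 0.0177 with an estimated correlation). Members of the Lce1 family can share reads, but the family's summed RPKM also differs, at 66.9 ± 3.7 in WT and 267.9 ± 4.8 in KO. Granular and cornified genes rose in 27 of 31 with 0 lower (28 and 0 adjusted over the list alone), with Hrnr, hornerin, at 2.53-fold and Sbsn, suprabasin, at 1.95-fold. Spinous genes rose in 18 of 21 with 0 lower (19 and 0 adjusted over the list alone, Dsc1 1.98-fold), and barrier lipid genes rose in 15 and fell in 2 of 35 (19 and 2 adjusted over the list alone, Aloxe3 2.01-fold, Dgat2 1.69-fold). The camera adjusted p-values are 5.2e-48, 1.9e-30 and 3.1e-16 (adjusted p = 0.0177, 0.0181 and 0.018 with an estimated correlation). Alarmin and stress genes rose in 12 and fell in 1 of 23 (14 and 1 adjusted over the list alone, Krt6b, a stress keratin, 2.39-fold; adjusted p = 4.6e-14, and adjusted p = 0.0416 with an estimated correlation). Sprr genes rose in 7 of 8 (8 adjusted over the list alone, Sprr1a 2.19-fold; adjusted p = 1.9e-11, and adjusted p = 0.0608 with an estimated correlation).

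Lower in KO basal cells were 14 of 23 cholesterol synthesis genes with 0 higher (17 and 0 adjusted over the list alone, Idi1 −0.38; camera adjusted p = 7.2e-10, and adjusted p = 0.0608 with an estimated correlation). Scd1, a sebaceous fatty acid desaturase, fell by 0.46 and the sebaceous list fell in 6 and rose in 1 of 12 (7 and 1 adjusted over the list alone, adjusted p = 0.00025, and adjusted p = 0.095 with an estimated correlation). Of 45 genes of the G2 and M phases 15 fell (27 adjusted over the list alone, median −0.12; Cdc20 −0.20; adjusted p = 1.4e-11, and adjusted p = 0.0496 with an estimated correlation), but 5 after rescaling. Regulators of the epidermis rose in 9 and fell in 3 of 43 (10 and 4 adjusted over the list alone, adjusted p = 0.0028, and adjusted p = 0.257 with an estimated correlation): Grhl1 1.31-fold and Klf4, a barrier factor, 1.12-fold were higher, Tfap2b lower. Basal keratinocyte genes rose in 4 and fell in 3 of 29, or in 7 and 1 after rescaling and 6 and 1 after quantile normalization (10 and 4 adjusted over the list alone, camera adjusted p = 0.039, and adjusted p = 0.143 with an estimated correlation), with Krt15 at −0.16, a call lost in the fit of basal libraries alone, without a filter and without WT basal library 2. Of the chromatin lists, KMT2 had 1 gene higher (Kmt2d, log2 0.19, not called without KO basal 1 or WT basal 2, without a filter or in the fit of basal libraries alone), SWI/SNF had 1 lower (Bcl11a, −0.17), DNA methylation 1 higher (Zbtb4, 0.20) and 1 lower (Gadd45a, −0.20), and the Polycomb, acetyltransferase and lysine methyltransferase lists had 0 genes called by limma (9, 3 and 2 at an unadjusted p under 0.05), with the same counts adjusted over the list alone except 2 lower for DNA methylation. The call on Bcl11a is lost without KO basal 1 or 2 or WT basal 1, that on Zbtb4 without any 1 of the basal libraries or without a filter, and that on Gadd45a without KO basal 1 or WT basal 2.

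Genes of other cells moved between the KO and WT basal libraries as well. In the erythroid list 4 of 5 genes fell (4 adjusted over the list alone, Hba-a2 −1.24, from 18.4 to 7.18 RPKM), with a camera adjusted p of 5.9e-07 (adjusted p = 0.0496 with an estimated correlation). T cell genes fell in 3 of 6 (4 adjusted over the list alone, Cd3g −0.84; adjusted p = 0.00096, and adjusted p = 0.0676 with an estimated correlation). Fibroblast genes fell in 4 of 15 with 0 higher (5 and 1 adjusted over the list alone, camera adjusted p = 0.26), or 1 after rescaling, and Langerhans and myeloid genes fell in 3 of 22 with 0 higher (3 and 0 adjusted over the list alone, camera adjusted p = 0.21). Melanocyte genes rose in 3 of 13 (6 adjusted over the list alone, Pmel log2 0.21; adjusted p = 9.5e-05, and adjusted p = 0.0571 with an estimated correlation). Krt27 of the hair follicle fell by 1.44 (2.06 to 0.130 RPKM), and the hair follicle list fell in 7 and rose in 1 of 25 (7 and 1 adjusted over the list alone, adjusted p = 0.014, and adjusted p = 0.095 with an estimated correlation). Xist rose (39.4 to 54.9 RPKM) and Ddx3y fell (11.1 to 8.46 RPKM). In each fraction 4 sex-linked genes were called lower in KO. The mix of the sexes may therefore differ between the KO and WT libraries, and it cannot be told apart from the genotype. In basal cells 876 of 12146 genes were called, 514 higher and 362 lower, with an all-gene median of −0.02, and 586 higher and 215 lower after rescaling. At a change of at least 2-fold 47 are called, 38 higher and 9 lower. Leaving out KO basal library 1 or 2, or WT basal library 1 or 2, gives 463, 542, 490 or 468 calls.

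In suprabasal cells, KO mice again had more RNA of Lce and late envelope genes than WT mice. Crct1 rose 3.0-fold (15.2 to 47.5 RPKM), Lce1m 2.99-fold (20.4 to 63.0 RPKM), Lce1b 2.7-fold, and Kprp, a keratinocyte proline-rich protein, 2.29-fold (n = 2 per genotype). Lor rose 1.81-fold (log2 0.86, adjusted p = 3.62e-06; 1330 ± 14.2 to 2408 ± 90 RPKM) and Asprv1, a protease that processes filaggrin, 1.85-fold. Krt71 and Krt27, keratins of the inner root sheath, fell by 2.75 (SE 0.068, adjusted p = 1.45e-07; 7.38 ± 0.598 to 0.248 ± 0.0148 RPKM) and 2.64. In the authors' deposited table the suprabasal KO to WT ratio is 1.81 for Lor, 3.11 for Crct1 and 0.0466 for Krt71.

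All 15 Lce genes rose in KO suprabasal cells (15 adjusted over the list alone, median 1.11; camera adjusted p = 1e-11, and adjusted p = 0.0518 with an estimated correlation). The summed family is at 81.4 ± 5.6 RPKM in WT and 225.9 ± 1.7 RPKM in KO. Granular and cornified genes rose in 29 of 31 with 0 lower (the same adjusted over the list alone, Ivl 1.64-fold, Hal 1.68-fold; adjusted p = 2.9e-17, and adjusted p = 0.0518 with an estimated correlation). Barrier lipid genes rose in 31 and fell in 1 of 35 (32 and 1 adjusted over the list alone, Elovl1, a fatty acid elongase, 1.63-fold, from 206 to 337 RPKM; adjusted p = 1e-13, and adjusted p = 0.0518 with an estimated correlation). Spinous genes rose in 19 of 21 with 0 lower (20 and 1 adjusted over the list alone, Krt77 1.78-fold, Krt1 1.11-fold, Krt10 1.15-fold; adjusted p = 6e-10, and adjusted p = 0.0876 with an estimated correlation). After quantile normalization 11 spinous genes are higher and 2 lower, and the calls on Krt1, Krt10 and Krt5 are lost, as they are without a filter. Basal keratinocyte genes fell in 14 and rose in 5 of 29 (14 and 6 adjusted over the list alone): Krt15 fell by 0.38 (1255 to 964 RPKM), Krt5 by 0.20, Trp63 by 0.18 and Itga6 by 0.11, with a camera adjusted p of 0.013 (adjusted p = 0.141 with an estimated correlation). Krt14 (log2 0.01, adjusted p = 0.658) and Mki67 (−0.06, adjusted p = 0.214) were not called. The suprabasal fraction holds much basal RNA, with Krt5 at 3889 RPKM in WT suprabasal against 8491 in WT basal libraries. Whether the share of basal cells in it differs between the genotypes was not tested, so these falls need not lie within suprabasal cells.

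Ribosomal protein genes rose in 70 of 78 with 0 lower (70 adjusted over the list alone, Rps15 1.22-fold; camera adjusted p = 8.2e-18, and adjusted p = 0.273 with an estimated correlation), but in 8 with 12 lower after quantile normalization. Respiratory chain genes rose in 35 of 73 with 0 lower (41 adjusted over the list alone, Ndufa6 1.19-fold; adjusted p = 4.1e-07, and adjusted p = 0.274 with an estimated correlation), but in 11 with 5 lower after quantile normalization. Cholesterol synthesis genes, lower in KO basal cells, rose in 11 and fell in 1 of 23 in KO suprabasal cells (the same adjusted over the list alone, camera adjusted p = 0.025, and adjusted p = 0.326 with an estimated correlation), or in 6 and 4 after quantile normalization. KMT2 genes fell in 9 and rose in 1 of 21 (9 and 2 adjusted over the list alone, Kmt2b −0.22; adjusted p = 0.0081, and adjusted p = 0.142 with an estimated correlation). Lysine methyltransferases fell in 10 and rose in 1 of 25 (11 and 2 adjusted over the list alone, adjusted p = 0.0051, and adjusted p = 0.119 with an estimated correlation). Of regulators, Cebpa, a factor of terminal differentiation, rose 1.3-fold and Junb by 0.47 in log2, while Tfap2b fell by 0.34 and Bcl11a by 0.28.

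Fibroblast, Langerhans and melanocyte markers were higher in the KO suprabasal libraries. Fibroblast genes rose in 14 of 15 (14 adjusted over the list alone, Col3a1 2.2-fold, from 5.86 to 14.1 RPKM; camera adjusted p = 9.6e-11, and adjusted p = 0.0518 with an estimated correlation). Langerhans and myeloid genes rose in 18 of 22 (19 adjusted over the list alone, C1qa 1.83-fold, H2-Aa 1.56-fold; adjusted p = 5.4e-10, and adjusted p = 0.0553 with an estimated correlation). Melanocyte genes rose in 11 of 13 (11 adjusted over the list alone, Dct 1.56-fold; adjusted p = 2.7e-06, and adjusted p = 0.0518 with an estimated correlation). Hair follicle genes rose in 12 and fell in 7 of 25 (12 and 8 adjusted over the list alone), with a median of 0.10, a mean of −0.24 and a camera adjusted p of 0.87; Tchh, trichohyalin of the inner root sheath, fell by 0.78. In suprabasal cells 4531 genes were called, 2620 higher and 1911 lower, with an all-gene median of 0.01, and with 2920 and 1831 after rescaling but 1935 and 2346 after quantile normalization. At a change of at least 2-fold 34 are called, 27 higher and 7 lower.

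**Figure D3:**
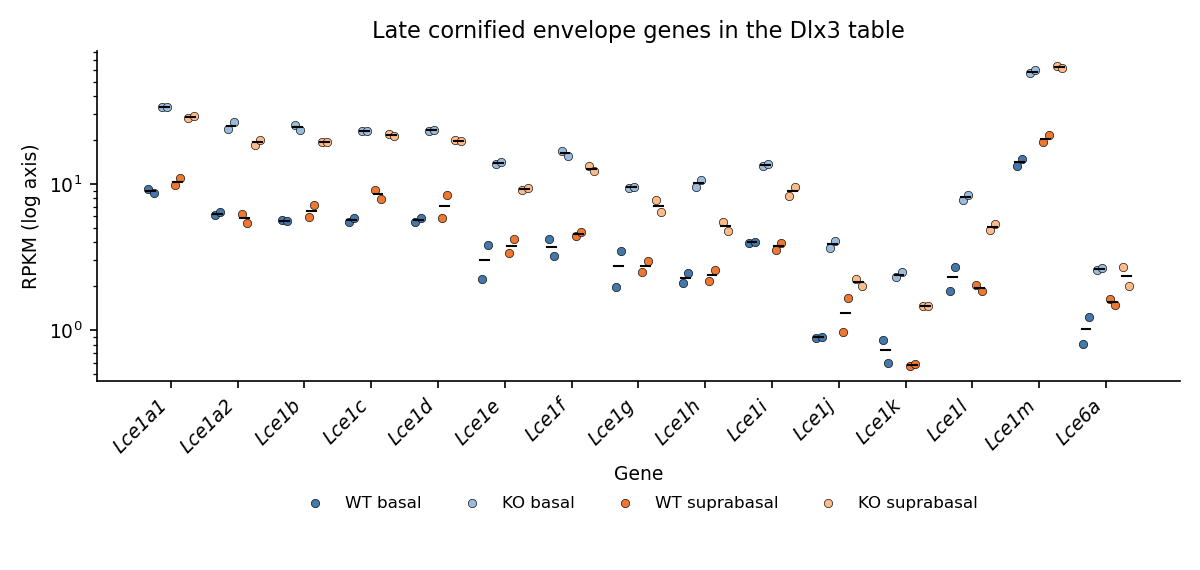
RPKM (log axis) of 15 Lce genes in the WT and KO basal and suprabasal libraries; points are libraries and lines means. All 15 genes lie higher in KO than in WT in both fractions.

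**Figure D4:**
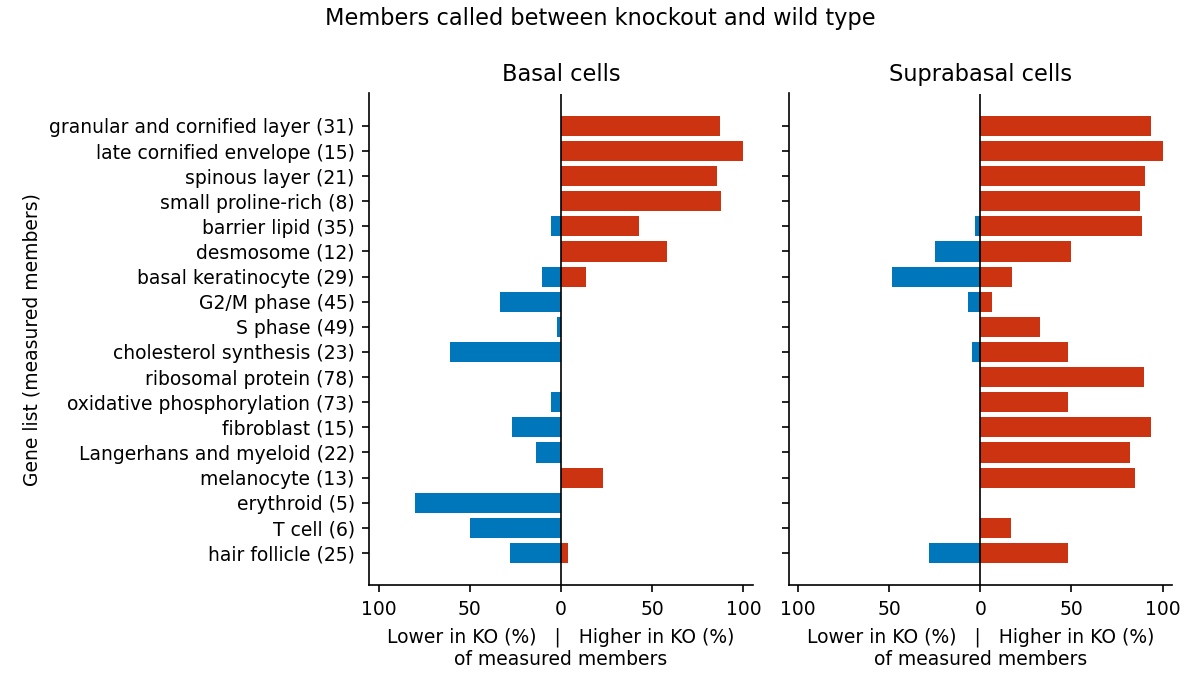
Percentage of measured members of 18 gene lists that were higher (red) or lower (blue) in KO than in WT, in basal (left) and suprabasal (right) cells; counts in parentheses are measured members. All 15 members of the Lce list are higher in both panels.

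The calls of both fractions overlap in direction: 356 genes were higher in KO in both (110.9 expected by chance) and 79 lower in both (57 expected), with 136 opposite. At a change of at least 2-fold 16 genes were higher in both (0.1 expected) and 2 lower. The expected numbers assume independent calls, but both comparisons use the same estimate of each gene's spread. The fractions of a genotype may also come from the same animals. Averaged over both fractions, Dlx3 fell by 1.59 (adjusted p = 9.52e-08) and Lce1m rose 3.44-fold, Crct1 3.41-fold, Lor 2.64-fold, Asprv1 1.72-fold and Ivl 1.68-fold (2 libraries per genotype and fraction). Krt1 and Krt10 rose 1.28-fold and 1.3-fold and Krt14 by 0.06 in log2, Krt5 fell by 0.10, Itga6 by 0.06 and Trp63 by 0.08, and Mki67 is at −0.04 (adjusted p = 0.265). The calls on Itga6 and Trp63 are lost after rescaling (adjusted p = 0.066 and 0.0806), and those on Krt1, Krt10, Krt14, Krt5, Itga6 and Trp63 with each library pair counted as 1 sample. Without a filter Krt14, Krt5 and Trp63 lose the call, without the intensity trend Itga6, Krt14 and Trp63, under quantile normalization Krt14 and Krt5, and with the replicate block Trp63. At least 1 of Krt14, Itga6 and Trp63 also loses its call with any library but WT basal 2 left out. Lce genes rose in all 15 cases, granular and cornified genes in all 31 and barrier lipid genes in 30 of 35 (15, 31 and 31 adjusted over the list alone). Their camera adjusted p-values are 3.3e-21, 1.1e-31 and 2.2e-20 (adjusted p = 0.0271 with an estimated correlation for each of the 3 lists). In the average fibroblast and melanocyte genes each rose in 11 cases with 0 lower, of 15 and 13 (11 and 11 adjusted over the list alone, adjusted p = 2.1e-08 and 1.4e-07, and adjusted p = 0.0353 and 0.0339 with an estimated correlation). In basal cells alone 0 fibroblast genes rose and 4 fell. The average calls 3226 genes, 1735 higher and 1491 lower, with an all-gene median of −0.01, or 2170 and 1136 after rescaling and 1449 and 1629 after quantile normalization. With the 2 libraries of each group averaged and counted as 1 sample, an alternative chosen after seeing the data, 282 genes are called, 242 higher and 40 lower. The spread in that fit is how the genotype difference varies between the fractions. It does not measure animals or pools, so these calls do not stand in for replication.

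The genotype difference itself was called as different between the fractions for 2737 genes, with an all-gene median of 0.03. The log2 KO to WT ratio was higher in suprabasal cells for 1755 of them and lower for 982. These calls rest on the spread between the 2 libraries of a group, which may be technical, so a difference between RNA pools is not separated from the genotype. The ratio of Lor was lower in suprabasal cells by 1.096 (SE 0.06, adjusted p = 3.37e-05, n = 2 per group), those of Krt1 and Krt10 by 0.40 and 0.36, and that of Krt71 by 2.79, while that of Dlx3 was higher by 0.60. The value of Krt71 restates its suprabasal fall, since in the authors' deposited table its basal KO to WT ratio is 1.19 (q = 0.388). The ratios of Krt5 and Trp63 were lower by 0.20 and that of Itga6 by 0.10, and Krt14 (−0.09, adjusted p = 0.0676), Ivl (−0.08, adjusted p = 0.644) and Mki67 (−0.04, adjusted p = 0.605) were not called. The call on Itga6 is lost without the intensity trend and with any library but WT basal 1 left out, that on Trp63 without a filter or without KO suprabasal 1, WT basal 2 or WT suprabasal 1, and that on Krt5 without a filter or under quantile normalization. Krt14 is called after rescaling (adjusted p = 0.0232), and the calls on Krt1 and Krt10 are lost without a filter. Lce genes had a lower ratio in 9 of 15 cases (14 adjusted over the list alone, median −0.48; camera adjusted p = 8.4e-09, and adjusted p = 0.0923 with an estimated correlation). Fibroblast and Langerhans genes had a higher ratio in 14 of 15 and 17 of 22 cases (15 and 18 adjusted over the list alone, adjusted p = 4.3e-12 and 2.1e-11, and adjusted p = 0.0923 for both with an estimated correlation). Cholesterol synthesis genes had a higher ratio in 14 of 23 cases (15 adjusted over the list alone, Sqle log2 0.45; adjusted p = 5.8e-08, and adjusted p = 0.108 with an estimated correlation). Quantile normalization turns the split of these calls to 1059 higher and 1362 lower. Leaving out KO basal library 1, WT basal library 2 or WT suprabasal library 1 gives 1673, 1591 or 1786 calls.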

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

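The tests of deeper sequencing and of the near-identical library pairs were chosen only after the results were seen, and the other tests of this part were planned. Among 110 groups of 4 values, 16 hold a library far from the other three, where chance gives about 1 in 20. In 13 of them it is Fvb/N suprabasal library 3. There the basal genes lie above the other suprabasal libraries, with the gap to the nearest library as a share of the range in parentheses: Col17a1 at 76.6 RPKM against 6.62 to 14.5 (0.887), Itga6 at 25.9 against 1.83 to 4.81 (0.876), Trp63 at 50.1 against 7.42 to 12.8 (0.873), and also Lamb3 (0.873), Itgb4 (0.875), Agrn (0.855), Bcam (0.863), Cd151 (0.945), Dnmt3a (0.856), Grhl2 (0.924) and Pmel (0.84). Fabp5, at 783 RPKM against 1388 to 1470 (0.882), and Calml3, at 67.1 against 213 to 219 (0.961), lie below the others in the same library. In suprabasal library 4, Flg2 is at 66.0 RPKM against 27.0 to 33.3 (0.838) and Sprr4 at 10.1 against 4.59 to 4.99 (0.927). Fvb/N basal library 4 has the fewest estimated reads of its group, 45.7 M against 52.9 to 54.3 M (0.837).

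More genes are above 0 in Fvb/N suprabasal libraries 3 and 4 (21583 and 21766) than in the other 6 Fvb/N libraries (18816 to 19194). Deeper sequencing is argued against for suprabasal library 3, which has 54.6 M estimated reads against 54.9 M in suprabasal library 2 (0.99 times). Suprabasal library 4 is the deepest, at 61.8 M, so a part of depth stays open there. Reads from genomic DNA are consistent with the share of 1458 olfactory and vomeronasal receptor genes above 0, which is 45.9% and 54.3% there and 6.2% to 16.9% in the other libraries, at least 2.71 times as high. RNA from dermal cells is also consistent with the values, since the median fibroblast gene is at least 3.78 times as high as in suprabasal libraries 1 and 2, with Col1a1 at 11.26 and 35.66 RPKM against 5.649 and 4.511, and Col1a2 at 12.98 and 26.28 against 4.353 and 3.919. Genomic DNA and dermal RNA both stay open, and the labels name no group that gives a biological explanation to test.

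The Dlx3 library pairs are nearly alike: their values differ beyond counting noise by a coefficient of variation of 0.1% to 2.1%. That each library comes from 1 animal is argued against, because Xist and Ddx3y are both at 5.45 RPKM or more in all 8 libraries. Both libraries of a group coming from 1 pool of RNA is consistent with the Y-linked genes, whose mean difference within a pair is at most 0.74 times the lowest between groups (0.099 against 0.135, log2). Libraries from separate pools of several animals stay open, and no biological explanation was tested.

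Other splits of the libraries were compared with the real ones. For Fvb/N, 1 of 35 splits, the real one, gives as many as 8584 genes, a share under 0.05. The other splits give at most 0 by limma (at most 5313 at an unadjusted p under 0.05, against 8787). Each of them mixes the fractions, which puts the difference between the fractions into the spread. The share also takes the libraries as interchangeable, which they are not if the numbers pair them, so chance is not called excluded. It is not settled whether the numbers pair these libraries. The 7 other splits that part the same-numbered libraries give at most 1281 genes at an unadjusted p under 0.05. These 7 are too few for a share under 0.05, so they do not decide. The split by the labels' run code calls 0 genes by limma (316 at an unadjusted p under 0.05). For Dlx3 KO against WT averaged over both fractions, 1 of 18 splits gives as many as 3226 genes and the highest other gives 2737. That other split sets KO basal and WT suprabasal libraries against the rest. It is the interaction contrast and holds genotype differences, so it does not show what chance gives. These splits are too few for a share under 0.05.

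The KO to WT log2 ratio was called as different between suprabasal and basal cells for 2737 genes, by a spread between libraries that may be technical. This is the same contrast as that highest other split. Among the named genes of the skin the ratio was higher in suprabasal cells for Dlx3 (0.605), Krt77 (0.537), a suprabasal keratin, Elovl1 (0.471) and Chil1 (1.187), and for Sqle (0.448) and Msmo1 (0.586) of cholesterol synthesis. It was lower for Krt5 (−0.199), Itga6 (−0.105), Trp63 (−0.199), Krt1 (−0.399), Krt10 (−0.365), Lor (−1.096), Hrnr (−0.678), Lce1c (−0.59) and Serpinb3a (−0.979), and for the hair follicle keratins Krt71 (−2.792) and Krt27 (−1.205). For Krt71 the value restates its suprabasal fall, since its basal KO to WT ratio in the authors' deposited table is 1.19 (q = 0.388). The dermal and immune genes Col3a1 (1.01) and C1qa (0.951) had a higher ratio in suprabasal cells. The values of the globins Hbb-bt (1.245), Hba-a2 (1.222) and Hbb-bs (1.179) restate their basal fall, since in suprabasal cells they are at most 0.292 RPKM in either genotype, where the added 1 holds the ratio near 0. The ratio was also higher for Hist1h2af (2.097), Rps15 (0.308) and Ndufa6 (0.279), while the small nucleolar RNAs Snord100 (−0.978) and Snora16a (−0.972) had a lower one. The calls on Hist1h2af and Snord100 are lost without a filter, without the intensity trend, and without KO suprabasal 1 or 2, WT basal 1 or 2 or WT suprabasal 2 (Snord100 also without WT suprabasal 1), and that on Snora16a without a filter. Calls on Hist1h2af and Snord100 rest on spreads that differ between groups, with Hist1h2af at 4.04 ± 3.58 RPKM in KO basal libraries.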

How the results depend on the processing

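Over all alternatives, 4906 of 5069 values of named genes have the same direction and call, 139 lose the call, 24 gain it and 0 are reversed. Most of these genes were named for large changes or a small p in the same data, which favours agreement. With a change of at least 2-fold the 7 comparisons call 4095 (Fvb/N), 1513 (WT), 1385 (KO), 47 (basal KO against WT), 34 (suprabasal), 26 (averaged) and 30 (interaction) genes, since that threshold asks for more. With the same threshold after rescaling, chosen after seeing the data, these are 3219, 1150, 1184, 45, 34, 26 and 32. The overlap of Fvb/N and WT is 1236 genes at 2-fold and 919 at 2-fold after rescaling. Averaging library pairs calls 282 genes for the averaged genotype comparison, with fewer samples and with another measure of spread. That spread is how the genotype difference varies between the fractions, not how animals or pools vary. Camera with an estimated correlation passes 0, 1, 9, 7, 0, 6 and 0 lists in the order above (3, 16, 17, 17, 13, 14 and 9 at an unadjusted p under 0.05). Leaving out 1 library gives 7828 to 9247 (Fvb/N), 10521 to 10871 (WT), 10538 to 10865 (KO), 463 to 796 (basal), 3088 to 4367 (suprabasal), 2221 to 2666 (averaged) and 1591 to 2306 (interaction) genes. The basal count moves by more than 1.5 times without KO basal library 1 (463) or 2 (542) or WT basal library 1 (490) or 2 (468), and the interaction without KO basal 1 (1673), WT basal 2 (1591) or WT suprabasal 1 (1786). A group left with 1 library borrows the spread of the others. Leaving out Fvb/N suprabasal libraries 3 and 4, or basal libraries 1 and 2, both chosen after seeing the data, gives 8942 or 8371 genes. With the replicate number as a block, the Dlx3 counts are 10862 (WT), 10878 (KO), 823 (basal), 4451 (suprabasal), 3157 (averaged) and 2654 (interaction). Quantile normalization turns the split of higher and lower calls in 3 comparisons (suprabasal, averaged and interaction); the cause was not tested. In the planted-change check 1.1-fold changes were recovered in 6% of basal and 12% of suprabasal cases. That check changed fewer genes than the real fits call, so these rates need not hold for the real fits. What depth limits was not tested.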

Other observations

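All tests of the Lce genes in this part were chosen only after the results were seen, and the test around the Dlx3 gene was planned. Secretory stress and tight junction genes also changed with the layer in the Dlx3 table. Unfolded protein response genes rose in 15 and fell in 6 of 23 in KO suprabasal against basal cells (the same adjusted over the list alone, Herpud1, an endoplasmic reticulum stress protein, 3.13-fold, camera adjusted p = 2.9e-06, and adjusted p = 0.0467 with an estimated correlation). In WT 13 rose and 8 fell (the same adjusted over the list alone, Herpud1 2.74-fold, adjusted p = 9.9e-05, and adjusted p = 0.0682 with an estimated correlation). Tight junction genes rose in 8 and fell in 5 of 17 in both genotypes (the same adjusted over the list alone), with Cldn4, a claudin, at 8.52-fold in WT and 11.5-fold in KO. Their camera adjusted p-values are 0.00013 and 6.7e-05 (adjusted p = 0.0848 and 0.0697 with an estimated correlation). After rescaling the unfolded protein list has 22 genes higher and 0 lower in WT and 21 and 0 in KO, and the tight junction list 14 and 1 in WT and 14 and 2 in KO. In Fvb/N suprabasal cells 4 unfolded protein genes rose and 9 fell, or 9 and 1 after rescaling. There 5 tight junction genes rose and 4 fell, or 11 and 2 after rescaling.

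Immediate early genes were higher in KO than in WT, averaged over both fractions, in 16 and lower in 1 of 30 cases (the same adjusted over the list alone, camera adjusted p = 4.5e-06, and adjusted p = 0.132 with an estimated correlation). Interferon response genes rose in 7 of 24 with 0 lower (7 adjusted over the list alone, adjusted p = 0.0003, and adjusted p = 0.0832 with an estimated correlation). The sex-linked list rose in 1 and fell in 4 of 5 (the same adjusted over the list alone, Eif2s3y −0.39, adjusted p = 0.0075, and adjusted p = 0.195 with an estimated correlation). A different mix of the sexes in the KO and WT libraries cannot be told apart from the genotype there. KMT2 genes fell in 7 of 21 (7 adjusted over the list alone, adjusted p = 0.024, and adjusted p = 0.16 with an estimated correlation), or in 4 after rescaling.

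Late cornified envelope genes were higher in both KO fractions. For the basal fraction, a higher share of cells like the average WT suprabasal cell is argued against as the whole cause, because in 15 of 15 genes the KO basal mean is above both WT means. The test does not cover a higher share of cells richer in Lce RNA than that average, which stays open. Reads shared between near-identical copies are argued against too, because the summed family is at least 2.78 times as high in KO (4.01 times in basal cells). A difference between animals or RNA pools other than the genotype cannot be told apart from the genotype: all 15 genes are called with each library pair averaged and counted as 1 sample, but each genotype and fraction may hold a single pool. The genotype, the biological explanation that the design gives, stays open beside it.

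A hypothesis is that strain differences linked to the KO allele, carried along near Dlx3 (chromosome 11, 95120119 to 95125296) in mice of mixed background, account for part of the changed genes. Within 10 Mb of Dlx3, 97 of 253 genes (38.3%) were called in the averaged comparison, against 3011 of 11411 (26.4%) on the rest of the autosomes, a ratio of 1.45 (95% interval 1.22 to 1.69, two-sided Fisher's exact p = 3.9e-05). The ratio lies between the bounds set in advance for and against the hypothesis, and the window also holds the type I keratin genes, which differ with skin layer, so the test leaves it open. Genes are not independent, and linked differences may be present in either genotype.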
